A study of Mus musculus with 5 samples.

How the data were processed

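The 5 libraries were made with droplet 3' kits, per the labels' protocols. Part 1 used cells dissociated with collagenase and treated with red cell lysis solution, and part 2 used nuclei isolated from frozen tissue. The deposited values are raw UMI counts per gene and barcode, with no normalization by the authors. Reads were counted with Cell Ranger 8.0.1, per the file headers, and the submitters' processing notes also name Seurat 5.4.0 and the builds GRCm39 and mm39. The annotation release is not given in the sources used here. Every deposited barcode had at least 500 UMIs, and 78334 genes were listed, the same in all libraries. A genome of an older build was not used here, so no coordinates are given and gene names are those of the files. Groups were taken from the sample labels. Replicate numbers are names only, since each group had 1 library.

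Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs in cells or 5% in nuclei. This removed 1814 barcodes of CFC-14d, 1752 of Random-14d, 214 of WT-naive, 154 of WT-CFC and 17 of KO-CFC. Doublets were scored by the method of Scrublet in an own implementation. The automatic threshold worked only in KO-CFC, where it removed 10.9% of barcodes. In the others it marked under 0.5%, so about 8% of highest score were removed: 7.71% of CFC-14d, 7.99% of Random-14d, 7.97% of WT-naive and 7.47% of WT-CFC. Median depth of deposited barcodes was 1997, 2077, 3988, 2220 and 2897 UMIs in CFC-14d, Random-14d, WT-naive, WT-CFC and KO-CFC.

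The libraries of each part were clustered together and the 2 parts were never mixed. Counts were scaled to 10000 per barcode, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used. A cluster was called like one of 26 marker classes when it had at least 3 markers at 2-fold or more, 20 or more barcodes, no more markers of another class than of its own among its 10 leading genes and a second-best class score of at most 0.65 of the best. Markers were fixed before the data were examined, together with the comparisons, the gene lists, the rule for named genes and 17 alternative settings. The scoring limits were set after the data were seen. Platelets were not among the marker classes, so platelet genes among the leading genes did not bear on a name, and a cluster of microglia-like cells in part 1 was led by such genes. Part 1 gave 57 clusters, of which 21 stayed unnamed, and part 2 gave 42, of which 21 stayed unnamed.

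Counts were summed per class and library, scaled to the class total as counts per 1000000 (CPM) and compared as log2 ratios with 0.5 counts added to each sum, in classes with at least 100 barcodes in each library and genes with at least 100 counts over both. Cells are not replicates, so no p-value or number of changed genes is given. CPM carry exact Poisson and shares exact Clopper-Pearson 95% intervals, which cover counting error only. A count of 0 was given a floor of 3 counts per class sum. For each of 28 gene lists with at least 4 measured members, the median log2 ratio was set against 10000 random lists of the same size matched on expression in 20 bins (2000 in the alternatives) and called high or low outside the 2.5 to 97.5 percentiles. This describes these libraries, not the conditions. Of 727 medians over all classes and comparisons, 199 were high, 90 low and 438 inside. Those of interest to the comparisons are described in the report.

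Genes were named by a rule. In each class described these were up to 12 highest and 12 lowest log2 ratios among genes at least 1.5-fold apart, whose CPM was at least 25% of that in the highest named class, without unnamed gene models, mitochondrial, ribosomal, haemoglobin and sex-linked genes. Csf2rb2, Csf2rb, Il3, Il3ra and Gfap were named always, as were the extreme members of lists with a given median. Some genes that this rule names are not reported here. To compare shares of nuclei with a UMI and reactive scores, barcodes were thinned to 1000 UMIs.

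Scripts were tested on simulated counts with 200 genes changed, in 20 simulations per comparison. In astrocytes, 97.8% of genes changed 2-fold passed 1.5-fold in CFC-14d against Random-14d (4261 genes), 96.2% in WT-CFC against WT-naive (5753), 96.7% in KO-CFC against WT-CFC (5163) and 97.0% in KO-CFC against WT-naive (4638). Of unchanged genes, 1.11%, 3.30%, 1.71% and 1.41% did so, and 4.56%, 3.99%, 5.65% and 5.39% of lists without change were called. In microglia, in the same order (12532, 1654, 3144 and 2902 genes), 98.96%, 97.4%, 96.4% and 97.0% of genes changed 2-fold and 0.306%, 1.63%, 2.43% and 2.20% of unchanged genes passed 1.5-fold, and 2.95%, 8.205%, 3.39% and 5.56% of lists without change were called. Other classes were not simulated. Apart from the planted changes, both libraries were drawn from 1 shared profile with counting noise only. These shares therefore do not cover differences between libraries or members of a list that move together. The 17 alternative settings chosen beforehand changed the filters, doublet removal, clustering, scaling, count minimum, free RNA correction, weighting of cells, thinning depth and the denominator of shares. A further 9 alternatives, chosen after seeing the data, took single clusters of astrocytes, left out an interferon-led or a platelet-led cluster of microglia or a cluster of oligodendrocytes with neuronal markers, or took microglia without UMIs of T or NK cell markers or with at least 1000 UMIs. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Oligodendrocyte-like cells of part 1 are not described in the report. Of their 6 calls of lists 0 were kept in every setting chosen beforehand, against 1 of 3 in astrocytes and 7 of 14 in microglia of part 1.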

Results

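RNA was counted in single cells and single nuclei of the mouse dentate gyrus, the part of the hippocampal formation whose granule neurons receive cortical input. Contextual fear conditioning (CFC) pairs a foot shock with a place. Part 1 held dissociated cells of wild-type mice 14 days after CFC (CFC-14d) or 14 days after random foot shocks (Random-14d). Part 2 held nuclei from frozen tissue of untrained wild-type mice (WT-naive), of wild-type mice 14 days after CFC (WT-CFC) and of mice 14 days after CFC whose title gives a Csf2rb2 knockout (KO-CFC). Each of the 5 groups consisted of 10 mice and was represented by 1 library, so no group had a replicate, no difference could be tested, and every interval below covers counting error only. The libraries held 126937815 UMIs (unique molecular identifiers, each standing for a captured RNA molecule) in 32827 barcodes for CFC-14d and 122920565 in 30515 for Random-14d. In part 2 they held 64716053 UMIs in 10968 barcodes for WT-naive, 68519389 in 13213 for WT-CFC and 38045642 in 8395 for KO-CFC. After filtering, 28621 and 26466 cells remained in part 1, and 9897, 12083 and 7462 nuclei in part 2, in the same order.

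The title of the series names signalling from IL-3 to CSF2RB2, a receptor subunit for this cytokine, so the targeted gene was examined before any comparison. Csf2rb2 RNA was present in the library labelled KO-CFC. Mossy cell-like nuclei, excitatory neurons of the hilus, held 180 of its 368 counts over all deposited barcodes of that library. They held 867 of 1208 counts in WT-CFC and 707 of 929 in WT-naive. There it stood at 91.1 CPM (counts per 1000000 UMIs of the class; 95% counting interval 78.3 to 105, 180 counts) in the library labelled KO-CFC, 113 CPM in WT-CFC (106 to 121, 867 counts) and 91.7 CPM in WT-naive (85.1 to 98.8, 707 counts). The log2 ratio was -0.31 (-0.56 to -0.08) for the library labelled KO-CFC against WT-CFC and 0.31 (0.16 to 0.45) for WT-CFC against WT-naive. Csf2rb2 was among the genes that led the mossy cell-like cluster, so its place there follows in part from the clustering. Over whole libraries it stood at 9.67 CPM (8.71 to 10.7) in the library labelled KO-CFC, 17.6 CPM (16.6 to 18.6) in WT-CFC and 14.4 CPM (13.4 to 15.3) in WT-naive. The measured level therefore goes against the knockout label. A 3' tag that lies outside the deleted part of the gene would check nothing, and which part was deleted is not given in the sources used here. The genotype tag of this library also names Csf2rb3 where its title names Csf2rb2. For these reasons it is called the library labelled KO-CFC throughout. Csf2rb2 and Csf2rb are paralogs of near-identical sequence, so their counts are uncertain where the counting could split reads between them.

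After each nucleus was thinned to 1000 UMIs, 12.3% of mossy cell-like nuclei (8.28 to 17.4) of the library labelled KO-CFC had a Csf2rb2 UMI, as did 11.02% (8.41 to 14.1) in WT-CFC and 9.13% (7.04 to 11.6) in WT-naive. The share in the library labelled KO-CFC was 6.80% when 1000 UMIs and 500 genes were required and 6.50% when 15% of barcodes were removed by doublet score. That in WT-CFC also fell below its interval, at Leiden resolution 2. The background in CA3 or CA2 pyramidal neuron-like nuclei was 0.152%, 0.323% and 0.474%. Median depths were 8505, 13747 and 10877 UMIs in mossy cell-like nuclei and 7322, 9818 and 8812 UMIs in CA3 or CA2 neuron-like nuclei. Thinning left out 1, 1 and 0 mossy cell-like nuclei, and the unthinned shares were 54.6%, 74.6% and 55.4%. No order of the libraries is read from the thinned shares, since their order differs from that of the CPM. Astrocyte-like nuclei held 3, 4 and 0 Csf2rb2 counts, so no difference in astrocytes was detectable at this depth. In part 1, Csf2rb2 stood at 13.9 CPM (276 counts) in microglia-like cells of CFC-14d and 13.1 CPM (294 counts) of Random-14d, and astrocyte-like cells held 3 and 2 counts. Csf2rb, the common beta subunit of the IL-3, IL-5 and GM-CSF receptors, was at 47.0 and 42.6 CPM in these microglia-like cells, a log2 ratio of 0.14 (0.01 to 0.27). It reached 89.4 and 92.3 CPM in monocyte-like cells. Il3ra, the alpha subunit of the IL-3 receptor, was at 24.7 and 27.7 CPM in monocyte-like cells and at 2.46 and 2.18 CPM in microglia-like cells. Il3 had 0 counts in all 5 libraries, which allows up to 0.0236 CPM in CFC-14d, 0.0244 in Random-14d, 0.0464 in WT-naive, 0.0438 in WT-CFC and 0.0789 in the library labelled KO-CFC, each the level of 3 counts.

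**Figure D1:**
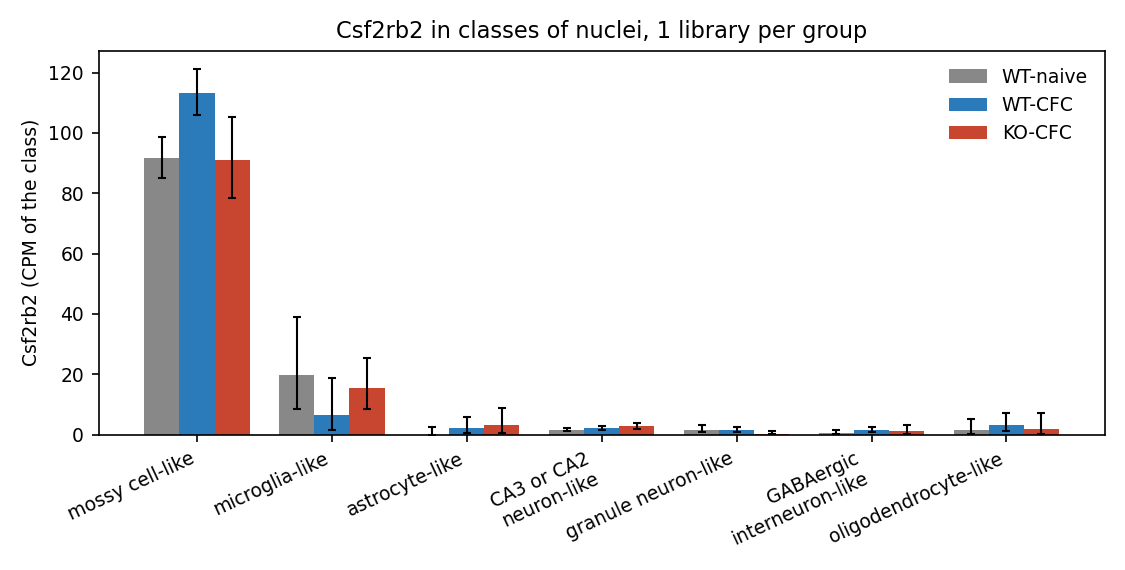
Csf2rb2 in CPM of 7 classes of nuclei, 1 library per group, with exact Poisson 95% intervals as error bars. Mossy cell-like nuclei stand at 91.7 in WT-naive, 113 in WT-CFC and 91.1 in the library labelled KO-CFC.

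Classes were named from markers fixed beforehand. Astrocyte-like barcodes made up 3.85% of CFC-14d (exact binomial 95% interval 3.63 to 4.08) and 3.25% of Random-14d (3.04 to 3.47). Microglia-like barcodes made up 31.8% (31.3 to 32.4) and 41.2% (40.7 to 41.8). In part 2, astrocyte-like nuclei made up 8.40% of WT-naive (7.86 to 8.96), 7.01% of WT-CFC (6.56 to 7.48) and 7.13% of the library labelled KO-CFC (6.56 to 7.74). Microglia-like nuclei made up 3.20% (2.86 to 3.57), 2.81% (2.52 to 3.12) and 9.64% (8.98 to 10.3). Dissociation, nuclei yield and the naming of clusters can set such shares: clusters left unnamed held 20.6% of CFC-14d and 3.75% of Random-14d, and 20.1%, 39.3% and 20.1% of WT-naive, WT-CFC and the library labelled KO-CFC. A limit on markers of another class, set after the data were seen, accounted for 15.7%, 38.3% and 1.93% of the part 2 libraries. A stricter limit on mitochondrial RNA turned the direction of the astrocyte share in part 1, and a limit of 1000 UMIs and 500 genes turned those of astrocytes and of microglia both in WT-CFC against WT-naive and in the library labelled KO-CFC against WT-CFC.

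CFC-14d was compared with Random-14d to ask what differs when shocks are tied to a learned place. In astrocyte-like cells, genes of cholesterol and lipid synthesis were higher in CFC-14d: 8 of 10 measured members were higher and the median log2 ratio was 0.35, above the central 95% of matched random lists (-0.13 to 0.20). Fdft1, squalene synthase, stood at 78.0 against 45.7 CPM (log2 ratio 0.76, 0.31 to 1.24), and Insig1, a sterol-regulated protein, at 45.3 against 25.9 CPM (0.79, 0.20 to 1.44). Abca1, which exports cholesterol, had a log2 ratio of -0.34 (-0.71 to 0.02). Gfap, the intermediate filament of reactive astrocytes, did not differ beyond counting error, at 150 and 159 CPM (log2 ratio -0.09, -0.36 to 0.18), and only 3 pan-reactive genes had enough counts, too few for a median. Thbs4, a secreted thrombospondin, was at 56.6 against 14.5 CPM (log2 ratio 1.94, 1.24 to 2.76), and Tnc, the matrix glycoprotein tenascin C, at 49.7 against 23.6 CPM (1.06, 0.46 to 1.72). Cdh4, a cadherin, had a log2 ratio of 1.09 (0.56 to 1.67), Aldh6a1, an enzyme of valine breakdown, of 0.96 (0.40 to 1.57), and Acads, of fatty acid oxidation, of 0.83 (0.25 to 1.45). Myoc was lower, at 25.1 against 68.6 CPM (log2 ratio -1.44, -2.02 to -0.90), as was Tnfrsf1a, a TNF receptor (-0.65, -1.25 to -0.06). All 11 measured mitochondrially encoded genes were higher (median 0.27; mt-Nd4 0.41, 0.35 to 0.47), and all 4 haemoglobin genes lower (median -0.46; Hbb-bs -0.47, -0.50 to -0.44). Haemoglobin took 5.34% of all UMIs in CFC-14d and 10.7% in Random-14d, Mir6236 stood at 106 and 73.1 CPM over whole libraries and Actg1 at 238 and 174 CPM. In the astrocyte-like cluster of high UMI counts alone the cholesterol median was 0.27. The cholesterol median left the called range when 15% of barcodes were removed by doublet score (0.18) or when cells were weighted equally (0.15). That of the mitochondrial genes did so at 1000 UMIs (0.15), at a stricter mitochondrial limit (0.13) and with each library clustered on its own (0.27).

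In microglia-like cells, interferon response genes were higher in CFC-14d, with 14 of 16 measured members higher and a median log2 ratio of 0.40 (random lists -0.06 to 0.10). Ifit3 stood at 15.8 against 7.07 CPM (log2 ratio 1.16, 0.88 to 1.44), Ifi27l2a at 36.3 against 20.4 CPM (0.83, 0.66 to 1.003) and Irf7, a transcription factor of the type I interferon response, at 8.03 against 4.58 CPM (0.81, 0.44 to 1.18). Psmb8, a subunit of the immunoproteasome, had a log2 ratio of -0.07 (-0.13 to -0.01). An Ifit3-led microglia-like cluster held 278 and 197 of these cells, and without it the median was 0.20. All 15 glycolysis and lactate genes were higher (median 0.22; Slc16a3, a lactate transporter, 0.40, 0.20 to 0.61; Pgk1 0.39, 0.28 to 0.50). JAK-STAT genes were higher in 10 of 13 (median 0.20; Socs1 0.34, Socs3 0.28). Glucocorticoid response genes were higher in 9 of 11 (median 0.18; Klf9 0.42, 0.12 to 0.73; Fkbp5, an inhibitor of the glucocorticoid receptor, 0.38, 0.26 to 0.50), with Sult1a1 at -0.35. Dissociation stress and heat shock genes were lower in 11 of 16 (median -0.13; Hspa1b -0.79, Hspa1a -0.70, Hsph1 -0.42), while Hspa5 was at 0.21 (0.19 to 0.23). Hspa1a and Hspa1b are near-identical copies, so the split of counts between them is uncertain. Ccl3, a chemokine, was at 396 against 641 CPM (log2 ratio -0.69, -0.73 to -0.66). Tmem267 was at 6.17 against 1.47 CPM (log2 ratio 2.06, 1.51 to 2.67), Ddit4, an inhibitor of mTORC1, at 0.92 (0.70 to 1.14) and Gdf15, a stress cytokine, at 0.91 (0.60 to 1.22). Cholesterol genes were higher in 9 of 13 (median 0.15; Idi1 0.76, Hmgcs1 0.35), a call that ended at a stricter mitochondrial limit (0.10) and with each library clustered on its own (0.12). All 4 haemoglobin genes were lower here too (median -0.70; Hbb-bs -0.73, -0.74 to -0.72). A microglia-like cluster led by Ccl4, Il1a and Atf3, genes that tissue dissociation can raise, was part of this class in both libraries. So was a cluster of 313 cells of CFC-14d and 606 of Random-14d with the platelet genes Clec1b, Ppbp and Gp9 among its leading genes, in which Ppbp, Pf4, Clec1b and Gp9 took 584 and 694 CPM, against 110 and 116 CPM in the other microglia-like cells. Without it, an alternative chosen after seeing the data, the 7 lists above kept their calls, with an interferon median of 0.41, and microglia-like cells made up 30.7% (30.2 to 31.3) and 39.0% (38.4 to 39.6).

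Interferon response genes were also higher in endothelial cell-like cells of CFC-14d, in 18 of 18 members, with a median log2 ratio of 0.46 (random lists -0.06 to 0.13). Ifi27l2a stood at 70.5 against 38.1 CPM (log2 ratio 0.89, 0.60 to 1.18), and Ifit2 and Ifit1 had log2 ratios of 0.81 (0.34 to 1.30) and 0.60 (0.31 to 0.91). The interferon-induced GTPases Gbp4 and Ifi47 were each at 0.95 (0.57 to 1.34 and 0.53 to 1.39). Of 15 classes with a median, this list was high in 3, with neuroblast-like cells the third, and low in 4, which were T or NK, neural stem or progenitor, choroid plexus epithelial and smooth muscle cell-like cells, the last with a median of -0.46. Only the calls of microglia, endothelial and smooth muscle cell-like cells held under every planned setting that gave a value. Pi16 was at 35.9 against 4.26 CPM (log2 ratio 3.04, 2.36 to 3.87), which was 1.93 when 15% of barcodes were removed by doublet score. Cholesterol genes were higher in 7 of 9 (median 0.25), a call that ended under 3 alternatives. In choroid plexus epithelial cell-like cells they were higher in 13 of 14 (median 0.36, random lists 0.03 to 0.20, with Fdft1 at 0.60, Idi1 at 0.51 and Fasn at 0.50), where the median of all genes was itself shifted by 0.11. Unnamed cluster 2, whose best class was also choroid plexus epithelial cell, was not part of this class. It held 4658 cells of CFC-14d and 271 of Random-14d, so the class left out far more such cells of 1 library.

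WT-CFC was compared with WT-naive to ask what differs between conditioned and untrained mice. In astrocyte-like nuclei, 12 of 13 cholesterol and lipid genes were higher in WT-CFC, with a median log2 ratio of 0.50 (random lists -0.18 to 0.25). Hmgcs1, an early enzyme of this synthesis, stood at 113 against 61.0 CPM (log2 ratio 0.89, 0.53 to 1.26) and Idi1 at 38.2 against 20.6 CPM (0.88, 0.26 to 1.55), while Abca1 was at -0.32 (-0.59 to -0.05). The direction of Abca1 turned with each library clustered on its own. In the astrocyte-like cluster not led by Gfap, which held most of this class in both libraries, the median was 0.47. Glucocorticoid response genes were higher in 7 of 8 (median 0.36). Zbtb16 stood at 234 against 70.3 CPM (log2 ratio 1.73, 1.42 to 2.05) and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at 104 against 41.8 CPM (1.30, 0.89 to 1.74), while Nr3c1, the glucocorticoid receptor, was at -0.09 (-0.41 to 0.22). In the cluster not led by Gfap alone this median was 0.21 and inside the random range. Gfap stood at 183 against 138 CPM (log2 ratio 0.41, 0.15 to 0.67).

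Among single genes of astrocyte-like nuclei, Pde10a, a cyclic nucleotide phosphodiesterase, stood at 606 CPM in WT-CFC against 123 in WT-naive (log2 ratio 2.30, 2.08 to 2.54). Tox had a log2 ratio of 1.89 (1.43 to 2.40), Adamts20, a matrix protease, of 1.77 (1.34 to 2.23), Crem, a cAMP-responsive transcription factor, of 1.63 (1.02 to 2.34) and Actg1, cytoplasmic actin, of 1.40 (0.98 to 1.87). Actg1, given below among RNA that can mark library quality, was also higher over the whole WT-CFC library. Its ratios here and in the classes below are therefore not particular to a class. Neat1, a nuclear non-coding RNA, was lower at 176 against 647 CPM (-1.87, -2.06 to -1.69), as was Gpd1 (-1.67, -2.27 to -1.11). Glycolysis genes were higher in 9 of 12 (median 0.26; Aldoa 0.83, Gapdh 0.68, Eno1 0.51), with Pfkfb3 at -0.47 (-0.94 to 0.01). Neurogenesis genes were lower in 5 of 6 (median -0.54; Igfbpl1 -1.98, Sox11 -0.90, Hopx -0.65), with Calb2 at 0.92, beside a share of neuroblast-like nuclei of 1.14% in WT-CFC and 3.45% in WT-naive. Mitochondrially encoded genes were lower in 9 of 11 (median -0.33), from mt-Co3 at -1.77 to mt-Nd3 at 1.82, and ribosomal protein genes in 14 of 19 (median -0.15; Rplp0 -0.60). Each of these 4 calls ended under 2 to 4 alternatives, and with each library clustered on its own the mitochondrial median was 0.0321 and the ribosomal one 0.25.

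**Figure D2:**
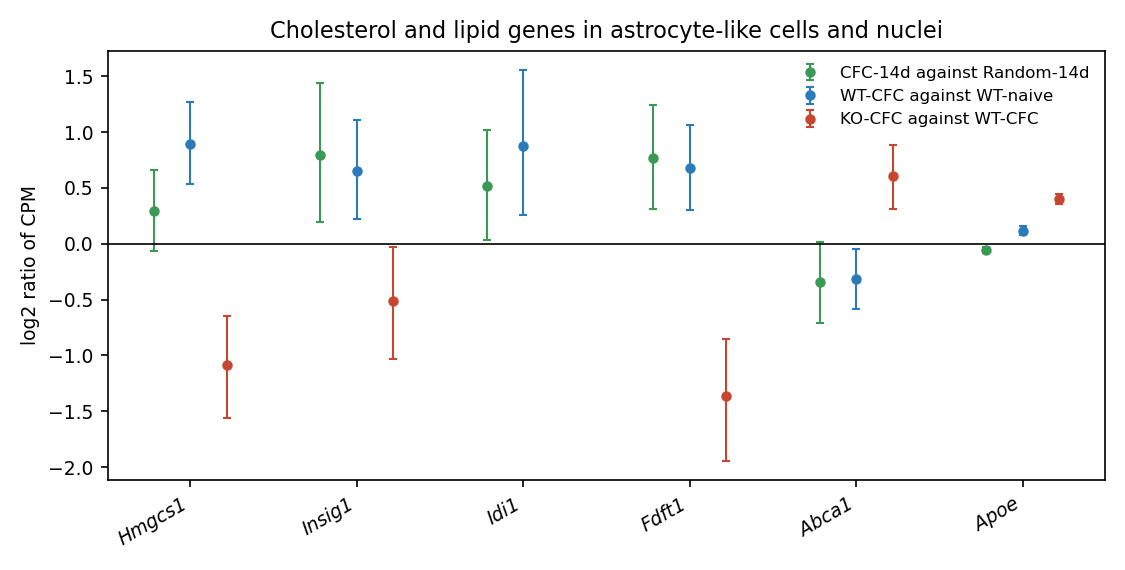
Log2 ratios of CPM for 6 cholesterol and lipid genes named in the text, in astrocyte-like cells or nuclei in 3 comparisons, with 95% counting intervals as error bars and 1 library per group. Medians of all measured list members are 0.35 for CFC-14d against Random-14d, 0.50 for WT-CFC against WT-naive and -0.82 for the library labelled KO-CFC against WT-CFC.

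Microglia-like nuclei of WT-CFC had more RNA of complement and phagocytosis genes, with 12 of 13 higher and a median log2 ratio of 0.54 (random lists -0.14 to 0.24). The subunits of complement C1q led them: C1qb stood at 720 against 282 CPM (log2 ratio 1.35, 1.04 to 1.67), C1qc at 702 against 312 (1.17, 0.87 to 1.48) and C1qa had a log2 ratio of 1.01 (0.78 to 1.25). These C1q genes are among the markers that name the class. Cst3, which encodes cystatin C, had a log2 ratio of 1.33 (1.21 to 1.46). Disease-associated microglia genes were higher in 6 of 7 (median 0.64; Tyrobp 0.86, Trem2 0.81, Fth1 0.64), while Apoe was lower (-0.73, -1.04 to -0.42). Homeostatic microglia genes, of which several also name the class, were higher in 8 of 9 (median 0.28; Tmem119 0.78, Sall1 0.56, Siglech -0.02), a call that ended under 3 alternatives. Apoe had a log2 ratio of 0.41 when clusters were drawn at Leiden resolution 0.5. In simulated counts without change, which held counting noise only, 8.205% of lists were called in this class and comparison.

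In oligodendrocyte-like nuclei of WT-CFC, Il33, an alarmin cytokine, stood at 277 against 79.1 CPM (log2 ratio 1.80, 1.51 to 2.12), Apod, a lipid carrier, at 556 against 194 CPM (1.51, 1.32 to 1.71) and Actg1 at 96.1 against 19.9 CPM (2.25, 1.69 to 2.90). All 7 stress and heat shock genes were higher (median 0.62; Hsph1 0.998, Hspd1 0.90), as were 8 of 9 glucocorticoid response genes (median 0.44; Sgk1 0.85, Zbtb16 0.80), 17 of 19 ribosomal protein genes (median 0.51; Rpl32 0.80) and all 13 myelin genes (median 0.41, random lists -0.18 to 0.31), beside a shift of 0.11 in the median of all genes of this class. Cnp, a myelin enzyme, stood at 274 against 142 CPM (log2 ratio 0.95, 0.71 to 1.19) and Opalin had a log2 ratio of 0.86 (0.62 to 1.10), while Mobp was at 0.01 (-0.12 to 0.14). A cluster of this class with markers of CA3 or CA2 neurons as its second class held 53 nuclei with 39.7% of the class's UMIs in WT-naive and 40 nuclei with 28.0% in WT-CFC. Without that cluster, an alternative chosen after seeing the data, 8 of 13 myelin genes were higher and their median of 0.19 was inside the random range (-0.0844 to 0.35), as were the medians of ribosomal protein genes (0.31) and glucocorticoid response genes (0.40). The stress median was then 0.42 (random lists -0.13 to 0.41), and Il33, Apod and Actg1 had log2 ratios of 1.62, 1.32 and 2.19. With 15% of barcodes removed by doublet score, the myelin median was 0.22, the stress median 0.46 and the glucocorticoid median 0.42, all inside the random range, and equal weight of nuclei gave 0.30 for myelin.

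Among neurons, mossy cell-like nuclei of WT-CFC had higher RNA of all 12 glycolysis genes (median log2 ratio 0.54; Gapdh 0.83, 0.57 to 1.09; Ldha 0.78, 0.48 to 1.10) and of all 8 stress and heat shock genes (median 0.51; Hsph1 0.79, Hspd1 0.73). Nr4a2, an activity-regulated nuclear receptor, was at 19.1 against 8.69 CPM (log2 ratio 1.13, 0.71 to 1.57). Loxl1, which cross-links matrix proteins, was at 2.35 against 21.4 CPM (log2 ratio -3.15, -3.98 to -2.48) and Scd3, a fatty acid desaturase, at 1.44 against 12.2 CPM (-3.03, -4.13 to -2.18). Cholesterol genes were higher in 10 of 14 (median 0.23; Scd2 0.73, Hmgcs1 0.62), which 5 alternatives ended. Interneuron-like nuclei had more RNA of the peptides Sst, at 441 against 149 CPM (log2 ratio 1.57, 1.47 to 1.67), and Npy, at 436 against 186 CPM (1.23, 1.14 to 1.32), both of which are among the markers that name this class. Beside this, unnamed cluster 0, at a median of 577 UMIs and with Sst and Npy among its markers, held 37.4% of WT-CFC and 14.7% of WT-naive, and over whole libraries Mir6236 stood at 139 against 47.6 CPM and Cmss1 at 4589 against 3230 CPM. Sst was at 70.3 CPM in astrocyte-like nuclei of WT-CFC and 88.9 CPM of WT-naive, and at 13.9 and 16.6 CPM in CA3 or CA2 neuron-like nuclei. The chemokine Cxcl14 had a log2 ratio of 1.28 (1.07 to 1.49). All 9 stress genes (median 0.51; Hsph1 1.45) and 12 of 13 cholesterol genes (median 0.34; Scd2 0.92, Insig1 0.90) were higher there, the latter a call that ended at 500 counts (0.22). In granule neuron-like nuclei, neurogenesis genes were lower in 8 of 9 (median -0.30; Igfbpl1 -1.67, Mki67 -0.79), with Calb2 at 0.998, beside the lower share of neuroblast-like nuclei, and a limit of 1000 UMIs gave -0.16, inside the random range. Immediate early genes stayed inside it, with a median of 0.10 (Nr4a2 0.87, Nr4a3 0.57). Il1rapl2 was lower in granule neuron-like nuclei (-1.13, -1.32 to -0.94). Actg1 was higher in mossy cell-like (1.80), interneuron-like (1.83) and granule neuron-like nuclei (1.25).

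The library labelled KO-CFC was compared with WT-CFC to ask what differs with the genotype given after the same training, although Csf2rb2 RNA does not bear out that label. Sex-linked and immune RNA, given below, also set this library apart, so no difference is assigned to the genotype. This comparison and that of WT-CFC with WT-naive use the same WT-CFC counts, with opposite sign. A gene high in WT-CFC there can therefore be low here without any change in the library labelled KO-CFC, and the reverse. In astrocyte-like nuclei all 4 measured pan-reactive genes were higher in the library labelled KO-CFC, with a median log2 ratio of 4.14 (random lists -0.59 to 0.61). Gfap stood at 926 against 183 CPM (log2 ratio 2.34, 2.16 to 2.52), Vim, another intermediate filament, at 209 against 11.6 CPM (4.14, 3.52 to 4.89), Serpina3n, a protease inhibitor, at 92.9 against 4.98 CPM (4.15, 3.23 to 5.39) and the interferon-induced chemokine Cxcl10 at 112 against 2.77 CPM (5.21, 4.08 to 6.99). All 7 measured interferon and antigen presentation genes were higher, with a median of 3.97 (random lists -0.52 to 0.48). Ifitm3 had a log2 ratio of 5.87 (4.84 to 7.45), Bst2 of 4.78 (3.93 to 5.93), H2-D1 of 3.99 (3.51 to 4.55), B2m of 3.36 (2.91 to 3.87), H2-K1 of 2.60 (2.30 to 2.93) and Stat2 of 1.47 (0.99 to 1.97). Only 4 of 13 pan-reactive and 7 of 18 interferon genes reached 100 counts over both libraries. A gene rare in WT-CFC reaches that only if it is high in the library labelled KO-CFC. The filter thus partly sets how many members were higher and the size of such medians, here and in the classes below. H2-T23 had a log2 ratio of 5.88 (4.66 to 7.94). The interferon-induced GTPase Iigp1 had 131 against 2 counts, a log2 ratio of 6.60 (5.04 to 9.98), and its paralog Iigp1c, with 207 against 0 counts, was at least 127-fold higher against a floor of 3 counts. Counts of the H2 genes and of the Iigp1 pair are uncertain where reads could be split between close copies. Different clusters held most of this class: one led by Gfap and C4b held 324 of its nuclei in the library labelled KO-CFC and 113 in WT-CFC, and the other held 208 and 734. Within the Gfap-led cluster alone the interferon median was 2.84.

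**Figure D3:**
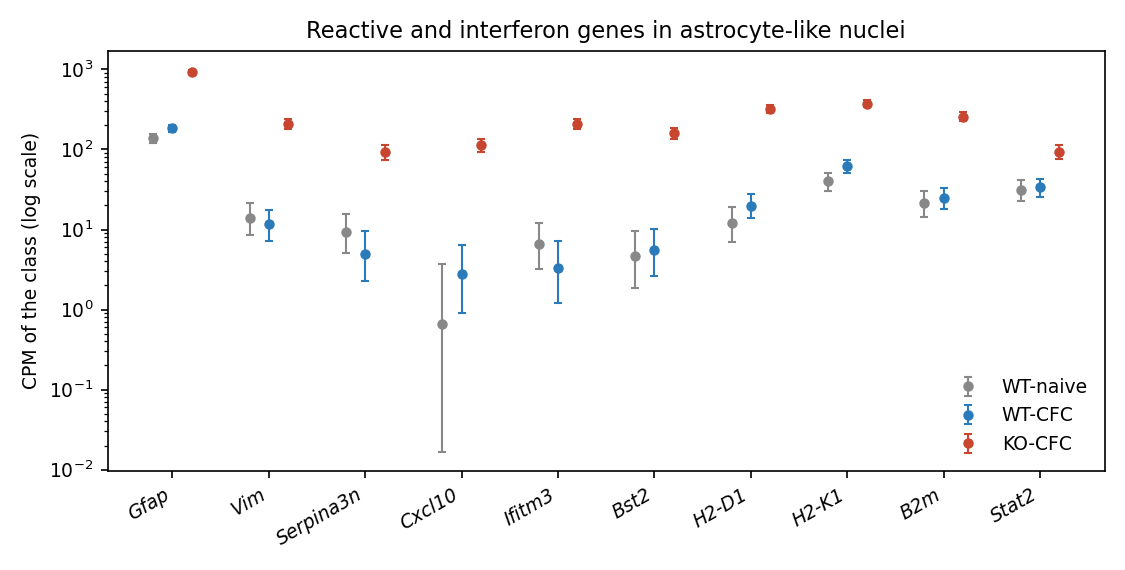
CPM (log scale) of reactive and interferon genes in astrocyte-like nuclei of the 3 part 2 libraries, with exact Poisson 95% intervals as error bars and 1 library per group. The library labelled KO-CFC stands above both wild-type libraries for all 10 genes, from Stat2 at 93.9 to Gfap at 926.

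Cholesterol and lipid genes of astrocyte-like nuclei were lower in the library labelled KO-CFC than in WT-CFC in 10 of 12, with a median log2 ratio of -0.82 (random lists -0.41 to 0.30). Fdft1 stood at 36.7 against 95.7 CPM (log2 ratio -1.37, -1.94 to -0.86) and Hmgcs1 at 53.1 against 113 CPM (-1.09, -1.56 to -0.65). Nsdhl, another enzyme of sterol synthesis, was at -1.77 (-2.50 to -1.15). Abca1 and the lipid carrier Apoe were higher (0.60, 0.31 to 0.89, and 0.40, 0.36 to 0.45). The median was -0.51 in the cluster not led by Gfap. Glucocorticoid response genes were lower in 6 of 8 (median -0.58; Zbtb16 -1.85, -2.27 to -1.48; Tsc22d3 -1.40, -1.96 to -0.91), while the metallothioneins Mt1 and Mt2 were higher (1.53 and 1.28); with 1000 UMIs required the median was -0.49 and inside the random range. Pde10a stood at 89.8 against 606 CPM (-2.75, -3.08 to -2.44), and Tox was at -1.84 (-2.47 to -1.30). Pde10a, Tox, Zbtb16, Tsc22d3 and Hmgcs1 were named above as higher in WT-CFC than in WT-naive, so these lower values are not separate results. Against WT-naive, the cholesterol and glucocorticoid medians of the library labelled KO-CFC were -0.38, at the edge of the random range, and -0.13, inside it. Disease-associated microglia genes were higher in 8 of 9 (median 1.23, with Cd9 at 1.75, Csf1 at 1.52 and Axl at -0.17), beside microglial RNA that, measured by C1qa, C1qb and C1qc, came to 7.67% (6.80 to 8.63) of the RNA of these nuclei against 0.659% (0.444 to 0.940) in WT-CFC. The reference for this share was the microglia-like class of each library. In the library labelled KO-CFC that class was mixed with nuclei of a cluster with T or NK cell markers, given below, so the share is uncertain. All 19 ribosomal protein genes were higher (median 0.96; Rplp0 1.72). Perineuronal net genes were lower in 4 of 7 (median -0.60; Hapln1 -1.33, Timp2 0.68), a call that 6 alternatives ended and a limit of 20 counts turned to 0.33.

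Other RNA differed with this library. Xist, expressed in female cells, stood at 834 CPM in its astrocyte-like nuclei against 3.87 in WT-CFC (log2 ratio 7.65, 6.70 to 9.07), and Eif2s3y, on the Y chromosome, at 14.3 against 118 CPM (-3.00, -3.94 to -2.27). Igkc, an immunoglobulin light chain of B lineage cells, had 794 counts there against 0, at least 488-fold higher against a floor of 3 counts. No class of B cells was named in part 2, so the naming rule could not leave out Igkc or MHC class II RNA as free RNA of such cells. Unnamed clusters 9 and 18, led by Iglc1, Igkc and Ighm and by Ighm and Cd74, held 12.2% and 3.75% of this library. They held 7 and 0 nuclei of WT-CFC and 7 and 3 of WT-naive. Over the whole library labelled KO-CFC immunoglobulin genes took 1049 CPM, against 3.84 CPM in WT-CFC and 3.21 CPM in WT-naive. Of RNA that can mark the quality of a library, Malat1, a nuclear RNA, took 18.0% of UMIs in the library labelled KO-CFC, 13.7% in WT-CFC and 15.7% in WT-naive. In the same order Cmss1 stood at 1022, 4589 and 3230 CPM, Lars2 at 401, 915 and 1070 CPM, Rn7sk at 45.1, 176 and 196 CPM and Mir6236 at 27.4, 139 and 47.6 CPM. Rn18s-rs5 stood at 9419, 12130 and 14219 CPM and Actg1 at 112, 63.0 and 18.5 CPM.

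In microglia-like nuclei, which were a single cluster, all 9 homeostatic genes, of which several also name the class, were lower in the library labelled KO-CFC (median log2 ratio -1.23, random lists -0.74 to 0.42). Gpr34 stood at 278 against 717 CPM (log2 ratio -1.37, -1.61 to -1.13), Tmem119 at 121 against 299 (-1.31, -1.68 to -0.94), Siglech at 278 against 681 (-1.29, -1.53 to -1.05), and the purinergic receptor P2ry12 at 442 against 885 (-1.004, -1.20 to -0.81). All 12 disease-associated genes were higher (median 1.55): Apoe had 4667 against 149 counts (log2 ratio 3.89, 3.66 to 4.14), Spp1, osteopontin, 126 against 1 (5.33, 3.40 to 11.22) and the receptor kinase Axl 105 against 0, at least 16.6-fold higher, while Ctsd was at 0.27 (0.11 to 0.43). All 10 interferon genes were higher (median 2.86), with Oasl2 at least 19.0-fold and Ifitm3 at least 19.7-fold higher, each against 0 counts in WT-CFC, and Psmb8 at 1.91 (1.12 to 2.91). The MHC class II genes Cd74 and H2-Eb1, at 1065 and 399 counts against 0, were at least 169-fold and 63.2-fold higher, beside Igkc at 1267 counts against 0. Gfap, an astrocyte gene, was also higher in these nuclei (3.27, 2.13 to 5.05), as were all 20 ribosomal protein genes (median 1.12; Rpl10 1.82). Jun was lower (-2.10, -2.51 to -1.70). T or NK cell markers took 159 CPM of these nuclei (135 to 186) against 15.1 CPM (6.06 to 31.1) in WT-CFC, and 71 of 719 nuclei held a UMI of such a marker against 7 of 339. With 1000 UMIs and 500 genes required, 371 of the 462 nuclei that remained fell in an unnamed cluster whose best class was T or NK cell, and the 87 that stayed in the microglia-like class were too few for a ratio. In the nuclei without such a UMI the medians were -1.14 for homeostatic, 1.31 for disease-associated and 2.72 for interferon genes, and in nuclei as named here with at least 1000 UMIs they were -1.39, 1.41 and 2.57, both alternatives chosen after seeing the data. The second set holds the 371 nuclei of that unnamed cluster, and at this depth a nucleus without such a UMI can still be a T or NK cell. Neither alternative can therefore show whether these differences belong to microglia. With a floor of 3 counts, each of these bounds covers counting error only. At Leiden resolution 0.5 the log2 ratio of Apoe was 2.65.

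In oligodendrocyte-like nuclei of the library labelled KO-CFC, C4b, a complement component, had 289 against 4 counts (log2 ratio 6.86, 5.66 to 8.91) and H2-T23 240 against 1 (8.18, 6.27 to 14.07). The MHC class I genes H2-D1, H2-K1 and B2m had log2 ratios of 5.86 (5.26 to 6.59), 5.00 (4.39 to 5.77) and 4.29 (3.66 to 5.06). Hmgcs1 (-1.52, -2.18 to -0.95) and Hsph1 (-1.43, -1.85 to -1.06) were lower. All 8 disease-associated microglia genes (median 0.82; Ctsd 1.03) and all 19 ribosomal protein genes (median 0.66; Rps2 1.28) were higher, beside a shift of -0.14 in the median of all genes and microglial RNA at 5.54% (4.81 to 6.34) against 0.607% (0.403 to 0.877). This share of microglial RNA rests on the same mixed reference as that of astrocyte-like nuclei. The cluster with CA3 or CA2 markers held 23.8% of the UMIs of this class in the library labelled KO-CFC and 28.0% in WT-CFC, and without it the medians were 0.78 and 0.65. In granule neuron-like nuclei, immediate early genes were higher in 8 of 11 (median 0.93, random lists -0.26 to 0.44): Nptx2, a secreted pentraxin, stood at 29.9 against 2.46 CPM (log2 ratio 3.57, 2.94 to 4.35), Arc at 18.8 against 3.08 CPM (2.59, 1.98 to 3.29) and Egr3 had a log2 ratio of 1.44 (1.04 to 1.87), while Nr4a3 was at -0.97. Penk, which encodes enkephalin, was at 57.4 against 6.76 CPM (3.07, 2.67 to 3.52). Interferon genes were higher in 5 of 6 (median 2.71; H2-K1 4.67, H2-D1 3.63; Stat2 -0.05), as were 7 of 9 neurogenesis genes (median 0.65; Igfbpl1 2.24, Sox11 1.48, Tubb3 1.18; Calb2 -0.47), all 20 ribosomal protein genes (median 0.91; Rps2 1.35) and Gfap (3.05, 2.43 to 3.796). Neuroblast-like nuclei, whose markers include Igfbpl1 and Sox11, made up 3.19% of the library labelled KO-CFC (2.80 to 3.61) and 1.14% of WT-CFC (0.960 to 1.35). Granule neuron-like nuclei came mostly from different clusters, one with 1354 nuclei of the library labelled KO-CFC and 269 of WT-CFC, which Xist also led, and one with 370 and 1125. In mossy cell-like nuclei, glycolysis genes were higher in 10 of 12 (median 0.997; Ldhb 1.52, Gapdh 1.505; Pfkfb3 -0.66), beside a shift of 0.13 in all genes. Glutamatergic synapse genes were lower in 19 of 22 (median -0.41; Grik2 -0.78, Shank2 -0.69; Nrgn 0.78) and cholesterol genes in 9 of 11 (median -0.35; Sqle -0.80, Hmgcs1 -0.55; Apoe 1.99). St8sia6 had 4 against 227 counts (-3.71, -5.76 to -2.50) and Hs3st4, a marker of CA3 or CA2 neurons, was at -2.21 (-2.37 to -2.06). The glutamatergic call ended at 1000 UMIs (-0.30) and at 500 counts (-0.37), and the cholesterol call at 500 counts (-0.19).

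Against WT-naive, the library labelled KO-CFC differs in training and in the genotype given, and also in sex-linked and immune RNA. Xist stood at 641.4 against 2.94 CPM, Y-linked genes at 42.79 against 274.2 CPM and immunoglobulin genes at 1049 against 3.21 CPM. These cannot be told apart here, so no difference of this library is assigned to any of them. Its astrocyte-like nuclei had higher pan-reactive genes in 4 of 4 (median log2 ratio 3.58; Vim 3.88, Serpina3n 3.28), with Gfap at 926 against 138 CPM (2.74, 2.53 to 2.97) and Cxcl10 at 110 counts against 1 (6.82, 4.89 to 12.72). All 7 interferon genes were higher (median 4.71; Bst2 5.00, Ifitm3 4.92, Stat2 1.58). The cholesterol list stayed inside the random range, at the edge of it, with 3 of 9 members higher and a median of -0.38 (random lists -0.38 to 0.42; Apoe 0.52, Fdft1 -0.69), and 5 alternatives put it below. Glucocorticoid response genes also stayed inside, at -0.13 (Mt1 1.78, Nr3c1 -0.57). In microglia-like nuclei, all 10 interferon genes (median 4.42; Oasl2 at least 16.6-fold higher, Stat2 2.38) and all 12 disease-associated genes were higher (median 1.81; Spp1 at least 17.4-fold higher, Csf1 3.58, Ctsd 0.91), and all 9 homeostatic genes were lower (median -0.89; Siglech -1.31, Gpr34 -1.09). Without doublet removal the homeostatic median was -0.22, inside the random range. A UMI of a T or NK cell marker was held by 71 of 719 of these nuclei against 4 of 317 in WT-naive. In nuclei without such a UMI the medians were 4.29 for interferon, 1.70 for disease-associated and -0.79 for homeostatic genes. That set can still hold T or NK cells, so it cannot show whether these differences belong to microglia.

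Relations between comparisons were described across genes, which are not independent replicates. The conditioning ratios of astrocytes in part 1 and part 2, which share no library, had a Spearman correlation of 0.13 over 3204 genes, with the same sign in 54.96%. Microglia gave 0.138 (same sign in 56.79%), oligodendrocytes 0.0646 (56%) and neuroblasts 0.0298 (50.51%). The ratios of the library labelled KO-CFC against WT-CFC and of WT-CFC against WT-naive share WT-CFC with opposite sign. Over 5040 genes in astrocytes their correlation was -0.45 (covariance -0.09), against -0.38 (-0.41 to -0.35; covariance -0.02) in 100 simulations of unchanged groups. With WT-CFC nuclei split at random between the 2 ratios, the mean over 20 splits was -0.31 (-0.33 to -0.28; covariance -0.07). Of 9 classes, the correlation lay below the simulated range in 2, astrocytes and oligodendrocyte precursors (-0.43 against -0.27), and inside it in 1. It lay above the range in 6, among them microglia (-0.20 against -0.54) and CA3 or CA2 neurons (-0.13 against -0.37), while the covariance was below the simulated mean in all 9. The simulation drew all libraries from the same profile, so its correlation rests on shared counting noise. Differences that the ratios do not share move a correlation towards 0. The place of a class against this range therefore does not show whether its ratios oppose each other. A split of nuclei removes shared counting noise and leaves what belongs to the library as a whole. The reactive score, the mean of log-scaled expression of 13 pan-reactive genes per astrocyte, was 0.219 in the library labelled KO-CFC (SD over nuclei 0.247), 0.0529 in WT-CFC (0.0840) and 0.0392 in WT-naive (0.0768). In part 1 it was 0.0651 in CFC-14d (0.106) and 0.0684 in Random-14d (0.115), a difference of -0.00332. After thinning to 1000 UMIs the difference between the library labelled KO-CFC and WT-CFC was 0.143 (0.166 unthinned), that of WT-CFC from WT-naive 0.00600 (0.0137) and that of CFC-14d from Random-14d 0.00107. Thinning left out 63 astrocytes of the library labelled KO-CFC, 48 of WT-CFC, 82 of WT-naive, 680 of CFC-14d and 483 of Random-14d.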

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

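All tests of explanations in this part were chosen after the results they bear on were seen. Values that stood apart in data outside the comparisons come first. Immunoglobulin genes took 1049 CPM of the library labelled KO-CFC, against 3.84 CPM in WT-CFC and 3.21 CPM in WT-naive, and T or NK cell markers took 52.88 CPM against 7.33 and 9.52. In part 1 immunoglobulin genes took 130.1 CPM of CFC-14d and 268.2 CPM of Random-14d. MHC class II genes took 196.4 CPM of the library labelled KO-CFC against 0.744 CPM in WT-CFC and 0.556 CPM in WT-naive. Xist took 641.4 CPM there against 1.81 and 2.94, and Y-linked genes 42.79 CPM against 276.5 and 274.2. Unnamed cluster 2 of part 1, led by Trpm3, Htr2c and Prlr with Mal, held 16.27% of CFC-14d against 1.02% of Random-14d. Its best class was choroid plexus epithelial cell, with oligodendrocyte second. Unnamed cluster 31, led by the neutrophil genes Camp, S100a9 and S100a8, held 1.419% of CFC-14d, or 406 cells, against 12 cells of Random-14d. Its best class was choroid plexus epithelial cell, with neutrophil second, so it was mixed. The named neutrophil-like cluster went the other way, with 73 cells of CFC-14d and 109 of Random-14d. Unnamed cluster 0 of part 2, led by Mir6236, Cmss1 and Lars2 with a median of 577 UMIs, held 37.45% of WT-CFC, 14.7% of WT-naive and 97 nuclei of the library labelled KO-CFC.

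Interferon and MHC genes were higher in the library labelled KO-CFC in every class with a measured list. Free RNA of immune cells in every droplet would keep interferon and immunoglobulin RNA in 1 ratio in all classes, and the ratio in astrocytes was 4.016 times (3.328 to 4.913) that in neuroblasts, the class with the lowest ratio. It was 1.132 (1.055 to 1.214) in astrocytes, 0.6124 (0.5087 to 0.7289) in oligodendrocyte precursors and 0.2819 (0.2338 to 0.335) in neuroblasts. These unequal ratios argue against such free RNA as the whole cause, though the contrast is smaller for classes other than neuroblasts. Microglial RNA in astrocyte droplets would bring 15.38% (13.41 to 17.59) of the astrocyte excess, which leaves most of it unaccounted for. The sex of the mice stays open, since Xist at 641.4 CPM and the remaining Y-linked RNA set this library apart from its controls. The genotype stays open as well, since Csf2rb2 in mossy cells was at 99.31% (83.84 to 117.1) of the WT-naive level and 1 library cannot part genotype, sex, infiltrating cells or the state of the mice.

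Csf2rb2 RNA was present in mossy cells of the library labelled KO-CFC. A level 32.98 times (22.2 to 50.66) that of CA3 or CA2 neurons in the same library goes against free RNA spread evenly over droplets. Csf2rb2 was among the genes that led the mossy cell-like cluster, so part of this fold follows from the clustering. How much of it does was not tested. A swap of the KO-CFC and WT-CFC labels with an allele that loses the 3' tag would leave WT-CFC without the RNA, and WT-CFC stood at 123.6% (111.8 to 136.7) of WT-naive. An allele that keeps its 3' end transcribed, or wild-type mice in the pool, stays open: the level was 80.35% (68.05 to 94.45) of WT-CFC, and the sources used here do not give the deleted part. With an allele that keeps the tag, a swap stays open as well, since this RNA would not show it. A single wrong label was not tested.

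Cholesterol and lipid genes were higher in astrocytes of both conditioned wild-type libraries. Oligodendrocyte RNA in astrocyte droplets would give list medians of only 0.001682 in part 1 and 0.000653 in part 2, against 0.35 and 0.50 observed. The hour of tissue collection stays open: evening minus morning clock genes differed by -0.227 (-0.3089 to -0.1459) in part 1 and by 0.2748 (0.1876 to 0.3608) in part 2, in opposite directions. Conditioning stays open too, since the list was at -0.384 in the library labelled KO-CFC against WT-naive, a comparison in which sex and the genotype label also differ.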

How the results depend on the processing

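Alternatives that take or leave out single clusters, or nuclei of a class by markers or UMIs, were chosen after the results were seen, and the others were planned. No paired analysis was possible because each group had 1 library and replicate numbers carry no pairing. Of the main values under the alternatives, 209 stayed within their interval or call, 19 moved, 3 weakened and 3 reversed, and among single genes and other lists described 3518 stayed, 121 moved, 46 weakened, 5 strengthened and 6 reversed. Over all classes, lists called high or low changed more often: of 3714 medians of called lists under the settings chosen beforehand, 3184 kept their call, 402 lost it and 128 turned. Of 289 such calls 129 were kept in every setting that gave a value, which were 35 of 106 in CFC-14d against Random-14d, 15 of 57 in WT-CFC against WT-naive, 35 of 60 in the library labelled KO-CFC against WT-CFC and 44 of 66 against WT-naive. For each value below the cause was not tested. The log2 ratio of astrocyte shares of CFC-14d against Random-14d (0.24) was 0.11 at 1000 UMIs and 500 genes, -0.0558 at a mitochondrial limit of 10%, 0.0475 at Leiden resolution 2 and 0.0493 with each library clustered on its own, and that of microglia (-0.37) was -0.43 at 1000 UMIs. For WT-CFC against WT-naive, astrocytes (-0.26) were at 0.23 at 1000 UMIs, -0.0400 at a mitochondrial limit of 1% and -0.77 without named neuronal classes in the denominator, and microglia (-0.19) at 0.32 at 1000 UMIs and -0.70 with that denominator. That denominator kept unnamed nuclei, which were 20.1% of WT-naive, 39.3% of WT-CFC and 20.1% of the library labelled KO-CFC. Its values therefore depend on the unnamed share and are not shares among non-neuronal nuclei. For the library labelled KO-CFC against WT-CFC, astrocytes (0.02) were at -0.43 at 1000 UMIs, -0.26 at the mitochondrial limit and 0.36 with that denominator, and microglia (1.78) at 2.11 with that denominator. At 1000 UMIs the microglia ratio was -1.30, where a cluster of 534 nuclei, 520 of them of that library, had T or NK cell markers with microglia second and stayed unnamed. Astrocyte cholesterol genes in CFC-14d against Random-14d were at 0.18 with 15% of barcodes removed by doublet score and at 0.15 with cells weighted equally. With each library clustered on its own, astrocytes of WT-CFC against WT-naive gave 0.0321 for mitochondrially encoded genes, 0.25 for ribosomal protein genes and 0.0505 for Abca1. Glucocorticoid genes there were at 0.21 in the cluster not led by Gfap, and Apoe of microglia was at 0.41 at Leiden resolution 0.5. In astrocytes of the library labelled KO-CFC against WT-CFC, sex-linked genes, 2 of them higher and 3 lower with a median of -2.21, were at 2.38 over 4 measured members at the mitochondrial limit and perineuronal net genes at 0.33 with 20 counts. The difference in reactive score was 0.143 there after thinning and 0.00661 in CFC-14d against Random-14d at a mitochondrial limit of 10%. The thinned share of mossy cell-like nuclei with Csf2rb2 in the library labelled KO-CFC was 6.80% at 1000 UMIs and 6.50% with 15% of barcodes removed. It was 6.95% in WT-CFC at Leiden resolution 2, and thinning to 2000 UMIs gave 24.2% in WT-CFC and 17.1% in WT-naive. Mossy cells of the library labelled KO-CFC clustered on its own, and several lists at 500 counts, gave no value. Depth limits the classes of few UMIs, among them microglia of WT-CFC and WT-naive with 464194 and 403960 UMIs and 1708 genes with enough counts, and per cell the astrocytes of part 1, at a median of 790 and 872 UMIs.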

Other observations

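Ribosomal protein genes were high in all 9 classes compared between the library labelled KO-CFC and WT-CFC, with medians from 0.57 to 1.12, and in all 9 against WT-naive, from 0.68 to 1.57, and 8 and 9 of these calls held in every planned setting that gave a value. Disease-associated microglia genes were high in the same 9 classes against WT-CFC, neurons included, from 0.79 to 1.55, of which 8 held likewise. Microglial RNA, measured by C1qa, C1qb and C1qc, came to between 1.68% (CA3 or CA2 neurons) and 8.96% (oligodendrocyte precursors) of the RNA of the other 8 classes in the library labelled KO-CFC, and to between 0.139% and 0.748% in WT-CFC. The reference was the microglia-like class of each library, which in the library labelled KO-CFC was mixed with nuclei of a cluster with T or NK cell markers. In CFC-14d against Random-14d, glycolysis and lactate genes were high in 13 of 15 classes and mitochondrially encoded genes in 10 of 15, while haemoglobin genes were low in 11 of 15 and high in 1, oligodendrocyte-like cells. Of these calls, 3 of the 13 for glycolysis, 5 of the 10 for mitochondrially encoded and 8 of the 11 low ones for haemoglobin genes held in every such setting, and the high one for haemoglobin genes was lost in at least 1. Cholesterol and lipid genes were high in 5 of 9 classes there, of which 1 held, and low in 1, fibroblast-like cells (-0.45), which was not kept. They were high in 4 of 6 in WT-CFC against WT-naive, of which 2 held, and low in 4 of 6 in the library labelled KO-CFC against WT-CFC, of which 3 held. Both of these comparisons use WT-CFC, with opposite sign. Clusters 9 and 18 of part 2, led by Iglc1, Igkc and Ighm and by Ighm and Cd74, held 913 and 280 nuclei of the library labelled KO-CFC among 927 and 283 in all.

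Neuroblast-like nuclei made up 3.19% of the library labelled KO-CFC, 1.14% of WT-CFC and 3.45% of WT-naive. CA3 or CA2 pyramidal neuron-like nuclei made up 18.0%, 18.2% and 28.4%, and granule neuron-like nuclei 23.1%, 11.5% and 12.2%.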
